A study of Mus musculus with 22 samples.

How the data were processed

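Total RNA from G-MDSCs was measured on the NanoString nCounter system with the mouse myeloid panel, in which each transcript is counted through a fluorescent barcode without amplification. Per the labels' protocols, Ly6G-positive cells were selected magnetically from dissociated tumours and passed over a column 2 times, entinostat was suspended in 0.5% methylcellulose, and vehicle mice received methylcellulose and isotype antibodies. The sample descriptions give vehicle as PBS with methylcellulose. The protocol says that studies were done with and without an anti-HER2 antibody and not which applies to these samples, so that treatment is unknown here.

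The deposited table gives normalized counts, a signal on a linear scale, for 22 samples, with 655 endogenous genes, 20 housekeeping genes, 8 negative and 6 positive controls. The software and the steps of the authors' normalization are not given in the sources used here, and the submitters' processing notes name limma without a version or a role. In the deposited values the geometric mean of the housekeeping genes was nearly level, from 172 to 194, while the median of the endogenous genes ran from 23.6 to 78.2 normalized counts, as in values scaled to the housekeeping genes. No source states this step. With such a scaling any change in the housekeeping genes shifts every other gene. No deposited value of a gene lay below 1. In each sample, 100% of the values up to 200 counts were whole multiples, within 0.1 count, of a fixed step of 0.400 to 9.78 normalized counts, and division by the step gave back barcode counts. The negative controls held 1 to 16 counts. These barcode counts were used for depth and for a count test as an added alternative.

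Groups were taken from the sample titles, and vehicle samples V1 and V2 were pooled with vehicle samples 1 to 4, since the labels do not say what sets them apart. There were 2 column names that each stood on 2 columns. These columns give the group and not the number, and are called samples a and b of entinostat plus anti-CTLA-4 and of the triple combination. By lane, triple combination sample a and vehicle sample 3 each lay beside samples of the other's group. An exchange of the 2 was not assumed, and the comparisons were also made without both. No column of values was left unused. Counts of no pair of samples differed by less than sampling noise (lowest chi-square per degree of freedom 3.17), so none was treated as a repeat. Of 675 gene names, 665 symbols and 664 accessions were found in the gene table for mouse, and 655 accessions led to the same symbol. The symbols of the deposited table were kept.

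The log2 of the normalized count plus 1 was fitted with limma 3.58.1 in R 4.3.3, with 5 group means in a single fit of all 22 samples (17 residual and 2.14 prior degrees of freedom), contrasts for 11 comparisons and a moderated F test. A gene was tested when its mean in at least 1 group exceeded the mean plus 2 SD of the negative controls on the log2 scale, 29.3 normalized counts, which left out 235 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05, two-sided, are called. The named genes follow a rule fixed before the data were examined, as were the groups and the tests. Of the genes called with all treated samples on one side of the reference mean, the 10 with the largest increase and the 10 with the largest decrease were named, or all that pass where fewer do, or the 3 with the smallest p in each direction where none passes. Always named against vehicle were Arg1, Nos2, Ptgs2, Stat3, S100a8, S100a9, Cd274, Cybb, Il10, Tgfb1, Vegfa and Cxcr2, and of each called list up to 4 members with the smallest p. Some genes that the rule names are not reported here. A set of 28 gene lists of myeloid functions, pathways and cell type markers was fixed at the same time. Of these, 22 had at least 3 tested genes and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists within a comparison. Lists of 10 epithelial and 10 pan-leukocyte genes were written later, after the tables had been read, and are only described. No background was subtracted, and its size on the normalized scale differed between samples. The negative controls averaged 4.1 to 7.1 counts in the entinostat samples, where 1 count was worth 1.77 to 2.32 normalized counts. They averaged 3.4 to 7 counts in entinostat plus anti-CTLA-4 samples 1, b and 3, where 1 count was worth 0.400 to 0.614. Fold changes of genes near background can therefore be too small or too large.

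On simulated data with the means and spreads of the 420 genes, 200 of them changed in entinostat against vehicle, limma recovered 71% of 100 genes changed by a log2 fold change of 1 and 96% of 100 changed by 2, with 7 false calls among 174. On counts simulated with the same changes edgeR 4.0.16, run with quasi-likelihood, recovered 67% and 100% with lane factors (1 false call of 168) and 68% and 100% with TMM factors (1 of 169). In both simulations genes were drawn independently, with as many raised as lowered, and the counts had a single fixed dispersion. The real genes varied together, with 73.9% of the variance on the first principal component, so these rates may not carry over to them. On the recovered counts edgeR called, for entinostat against vehicle, 189 genes with TMM and 151 with lane factors. The alternatives were other scalings (median centring, quantile normalization, centring on the housekeeping mean), no filter and a stricter filter, a pseudocount of 10, and a trend with robust priors. Others were sample weights, only the 2 groups compared, vehicle without V1 and V2 or with these averaged into samples 1 and 2, the replicate number as a block, and each sample left out in turn. Chosen after seeing the data were cartridge as a block or a single cartridge, edgeR on the recovered counts, leaving out the sample of lowest depth together with entinostat plus anti-CTLA-4 sample a, leaving out triple combination sample a and vehicle sample 3, the epithelial mean or Cdh1 as a covariate, and splits that exchange samples only within a cartridge. Permutation p-values of correlations used 1e+05 permutations, two-sided. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.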

Results

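Transcript levels were measured in granulocytic myeloid-derived suppressor cells (G-MDSCs), neutrophil-like cells that can restrain T cells, isolated from mammary tumours of mice. The tumours grew from NT2.5 cells, a line from a spontaneous mammary tumour, implanted at 50000 cells into the mammary fat pad of female neu-N mice, which carry a rat neu (HER2) transgene. Treatment began 3 days after implantation and lasted 3 weeks. Entinostat, an inhibitor of class I histone deacetylases, was given daily by mouth at 5 mg/kg. Anti-PD-1 and anti-CTLA-4, antibodies that block checkpoint receptors on T cells, were given 2 times a week at 100 µg per mouse. The 22 samples formed 5 groups: vehicle (6 samples), entinostat alone (4), entinostat plus anti-PD-1 (4), entinostat plus anti-CTLA-4 (4) and entinostat plus both antibodies, called the triple combination (4). No group received an antibody without entinostat. The stated aim was to look for transcript changes that could account for an impaired function of these cells after treatment.

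Of the 655 endogenous genes on the panel, 420 lay above background in at least 1 group and were tested. Recovered barcode counts per sample ran from 23296 in triple combination sample 2 to 443821 in entinostat plus anti-CTLA-4 sample 1, with a median of 179364. In the sample of lowest depth a single barcode count was worth 9.78 normalized counts, against 0.400 in the deepest, so levels near the background limit of 29.3 normalized counts were imprecise there. The samples were run on 2 cartridges. Cartridge 1 held 3 vehicle samples, all samples of entinostat alone and of entinostat plus anti-PD-1, and 1 sample of the triple combination, and cartridge 2 held 3 vehicle samples, all samples of entinostat plus anti-CTLA-4 and 3 of the triple combination. By lane, triple combination sample a lay between vehicle samples 2 and 4 on cartridge 1, and vehicle sample 3 lay next to the other triple combination samples on cartridge 2. No source used here accounts for this order, the groups given by the labels were kept, and the comparisons were also made without both samples. The labels do not tie each sample to a separate animal, so p-values measure only the spread between these samples, which could be technical. Fold changes are on the log2(normalized count + 1) scale with their standard errors (SE), and adjusted p-values are from limma with Benjamini-Hochberg adjustment over the 420 genes, two-sided, unless another tool is named. Means of normalized counts are given with the standard deviation (SD).

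**Figure D1:**
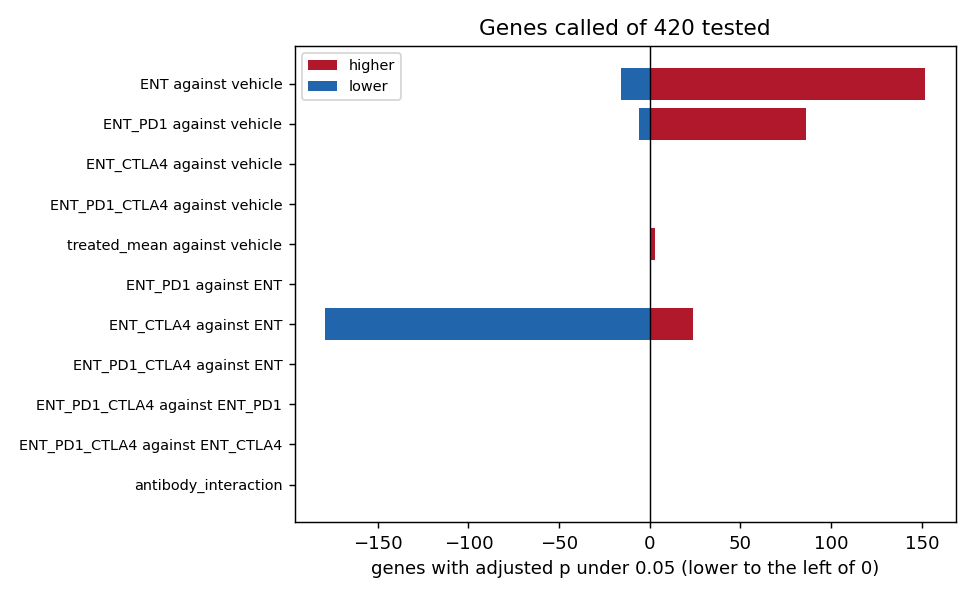
Number of genes with an adjusted p under 0.05 (limma) in each pairwise or pooled comparison, of 420 tested; bars to the right are genes higher and bars to the left genes lower in the group named before "against". Entinostat alone against vehicle gave 152 higher and 16 lower genes, entinostat plus anti-CTLA-4 against entinostat alone gave 24 higher and 179 lower. After each sample was centred on its median, which removes a shift shared by most genes, these splits became 95 and 81, and 121 and 104.

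The comparison of entinostat alone with vehicle asked what the drug did to the G-MDSC transcript profile. Neutrophil genes and inflammatory genes were higher after entinostat, and so were pan-leukocyte genes. The median log2 fold change was 1.73 for the neutrophil and 1.47 for the pan-leukocyte genes. S100a9, a subunit of the calcium-binding protein calprotectin of neutrophils, stood at 18565 ± 5130 normalized counts (SD, n = 4) after entinostat and 5879 ± 4373 (SD, n = 6) in vehicle, a log2 fold change of 1.85 ± 0.44 (SE, limma adjusted p = 0.00796). It was higher than the vehicle mean in 4 of 4 samples, as were the genes S100a8 and Cxcr2. Its partner S100a8 changed by 1.83 ± 0.46 (adjusted p = 0.00911), and Cxcr2, a chemokine receptor that draws neutrophils to inflamed tissue, by 1.72 ± 0.38 (adjusted p = 0.00769). Arg1, the arginine-degrading enzyme often used as a mark of suppressive myeloid cells, stood at 56.3 ± 23.8 against 60.4 ± 38.8 normalized counts. Its mean count was lower and its log2 mean higher after entinostat, a log2 fold change of 0.045 ± 0.49 that was within the spread (adjusted p = 0.938) and was negative after median centring, quantile normalization or TMM scaling.

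In all, 168 of the 420 genes passed, 152 higher and 16 lower, and in 149 and 15 of these every entinostat sample lay on the same side of the vehicle mean. Among the largest increases were those in Selp (log2 fold change 3.00 ± 0.95, adjusted p = 0.0200), the cytokine Il6 (2.74 ± 0.89), the monocyte-attracting chemokine Ccl8 (2.63 ± 0.97), the pentraxin Ptx3 (2.46 ± 0.79) and Sele (2.22 ± 0.66). Others were in the small GTP-binding protein Gem (2.20 ± 0.77), Icosl, a co-stimulatory ligand for T cells (2.19 ± 0.42, adjusted p = 0.00396), the receptor phosphatase Ptprb (2.11 ± 0.69) and Ccl7 (2.07 ± 0.70). Selp and Sele encode selectins of activated endothelium. The 10 largest decreases were smaller, and were in the histone gene Hist2h2aa1 (-0.73 ± 0.13, adjusted p = 0.00305), S100a4 (-0.72 ± 0.16), the growth factor receptor gene Pdgfra, carried by fibroblasts (-0.64 ± 0.19), urokinase Plau (-0.60 ± 0.18) and the collagen gene Col11a1 (-0.55 ± 0.17), and in 5 more. These were Dusp6 (-0.49 ± 0.15), Ptprk (-0.44 ± 0.16), Crip1 (-0.42 ± 0.13), E-cadherin Cdh1 of epithelial junctions (-0.41 ± 0.15, adjusted p = 0.0418) and Cd151 (-0.39 ± 0.13).

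Of the 14 measured genes of neutrophil granules and maturation, 13 rose, and 13 when adjusted over the list alone, with a median log2 fold change of 1.73. Among the members with the smallest p were the G-CSF receptor Csf3r (1.72 ± 0.37, adjusted p = 0.00769), Cxcr2 and Trem1, a receptor that amplifies inflammation (1.80 ± 0.42). The list stood apart from the other genes by limma camera with a preset correlation (adjusted p = 0.00337), and not with an estimated one (adjusted p = 0.912 with an estimated correlation). Of 22 genes of NF-kB and TNF-induced inflammation, 17 rose and 19 when adjusted over the list alone, median 1.38 (camera adjusted p = 0.0126, and 0.912 with an estimated correlation). The cytokine Il1b changed by 1.67 ± 0.40 (adjusted p = 0.00796), and Tnfaip3 (1.60 ± 0.39), Nfkbiz (1.09 ± 0.29) and Nfkbia (1.12 ± 0.30) rose with it, of which Tnfaip3 and Nfkbia encode inhibitors of NF-kB that are themselves its targets. After median centring the median log2 fold change was 1.19 for the neutrophil genes and 0.84 for the NF-kB genes, and all 14 neutrophil genes had a positive fold change under median centring, quantile normalization and TMM scaling.

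Suppressive effectors of myeloid cells were mixed. Of 15 measured genes 10 rose, and 12 when adjusted over the list alone, but the list did not stand apart from the other genes by camera (adjusted p = 0.0599), while fry, which does not compare a list with other genes, called it higher (adjusted p = 0.0104). Without triple combination sample a and vehicle sample 3 camera called the list too. Where all 15 fold changes were positive with the deposited scaling, 9 were positive after median centring and 6 with TMM. Ptgs2, the cyclooxygenase that makes prostaglandin E2, rose by 1.34 ± 0.42 (adjusted p = 0.0204). Stat3 (0.33 ± 0.11, adjusted p = 0.0218) and the angiogenic factor Vegfa (0.45 ± 0.17, adjusted p = 0.0479) passed with the deposited scaling, and their fold changes were negative under 3 other scalings, median centring, quantile normalization and TMM. The PD-L1 gene Cd274 (1.56 ± 0.65, adjusted p = 0.0616), the NADPH oxidase subunit Cybb (0.89 ± 0.64, adjusted p = 0.263, negative with TMM) and Tgfb1 (0.50 ± 0.22, adjusted p = 0.0830, negative under all 3 scalings) did not pass. Nos2 and Il10 were below the background limit in every group and were not tested.

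Markers of other cells moved beside these groups. Of 10 genes carried by all leukocytes, 10 rose (median log2 fold change 1.47, 0.93 after median centring), while of 10 epithelial genes 3 fell (median -0.26, and -0.80 with 6 lower after median centring). Both of these lists were written after the tables had been read. The mean of the epithelial genes was 7.31 ± 0.10 after entinostat (SD, n = 4) and 7.55 ± 0.23 in vehicle (SD, n = 6) on the log2 scale. None of the 10 monocyte and macrophage markers passed (median 0.64). Of 4 endothelial markers 2 rose, and 2 when adjusted over the list alone (median 1.86, camera adjusted p = 0.661), the selectins Selp (3.00 ± 0.95) and Sele (2.22 ± 0.66), and of 4 dendritic cell markers 1 rose, and 1 over the list alone (median 0.70, camera adjusted p = 0.661). Of 9 fibroblast and matrix genes 2 rose and 1 fell, and 4 passed over the list alone (median 0.64, camera adjusted p = 0.661). The median of the dendritic cell markers was -0.079 after quantile normalization and -0.030 with TMM, and that of the fibroblast and matrix genes -0.55 with TMM. Of these 4 lists fry called 1, the dendritic cell markers (adjusted p = 0.0412). The median log2 fold change of all 420 genes was 0.50, and the split of 152 higher and 16 lower became 95 and 81 after median centring, 88 and 87 after quantile normalization, and 57 and 132 with edgeR and TMM factors. These 3 scalings remove a shift shared by most genes by construction. More even splits and turned signs of genes with small folds follow in part from that. They do not show which scaling is right. Cartridge 1 alone gave 134 genes and the fit with cartridge as a block gave 169, with median log2 fold changes over the 152 higher genes of 1.32 and 1.45 against 1.36 for all samples. The count fell to 54 without vehicle samples V1 and V2, to 98 without entinostat sample 2 and to 80 without entinostat sample 3. Without entinostat plus anti-CTLA-4 sample a 5 lists were called, and 6 without triple combination sample a and vehicle sample 3. The count of genes rose to 298 with sample weights, and was 0 with the epithelial mean and 2 with Cdh1 as a covariate.

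**Figure D2:**
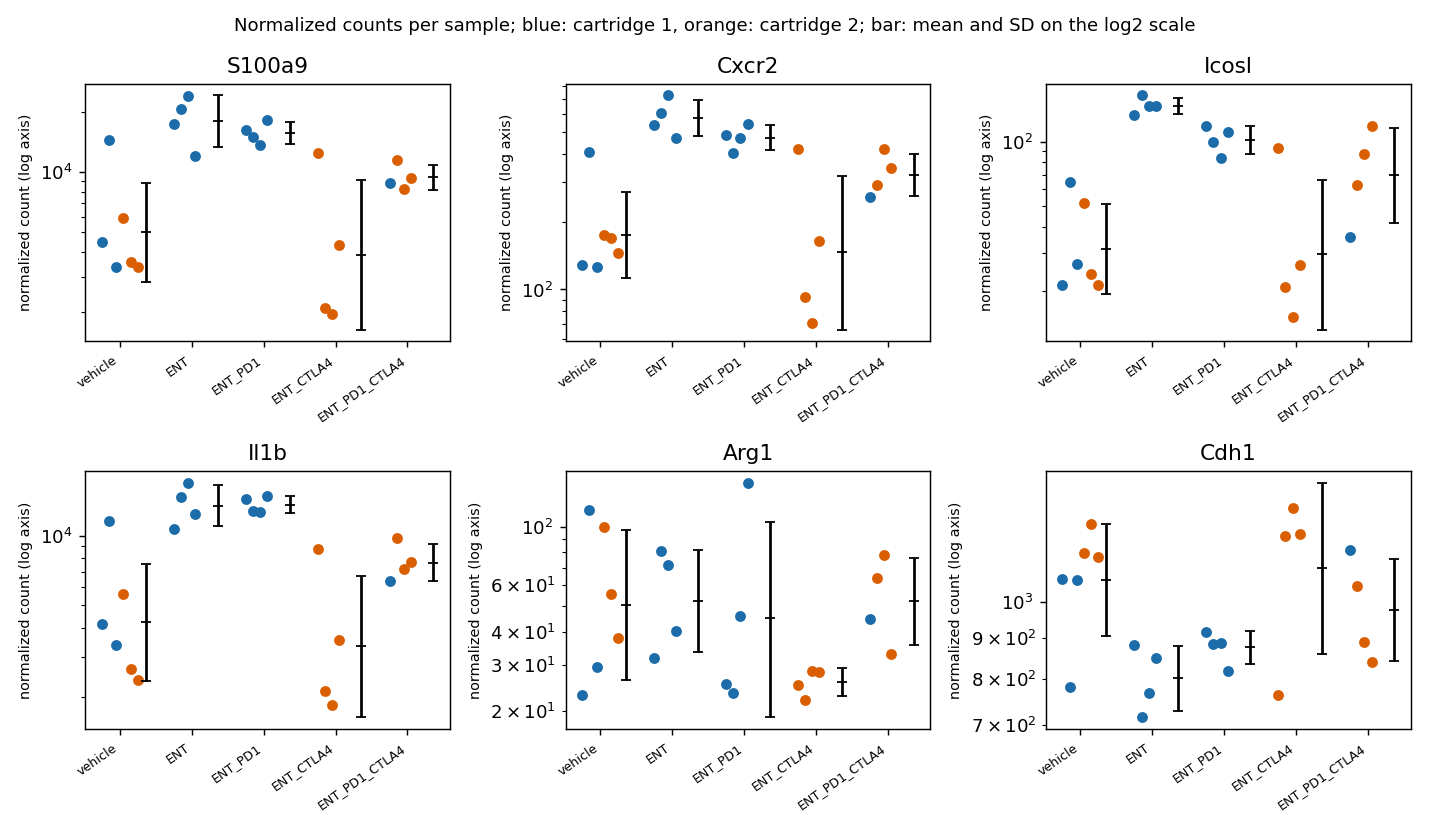
Normalized counts of S100a9, Cxcr2, Icosl, Il1b, Arg1 and Cdh1 in each sample, on log axes; blue points are cartridge 1, orange points cartridge 2, and the bar beside each group is its mean and SD on the log2 scale. S100a9 averaged 18565 normalized counts after entinostat alone and 5879 in vehicle. In S100a9 and Cxcr2, vehicle sample 2 lay above the other vehicle samples and sample a of entinostat plus anti-CTLA-4 above the other 3 of its group.

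Entinostat plus anti-PD-1 was compared with vehicle to ask for the effect of the pair. Again neutrophil, inflammatory and pan-leukocyte genes rose, with S100a9 at 15777 ± 1974 normalized counts (SD, n = 4) against 5879 ± 4373 in vehicle (SD, n = 6). In all 92 genes passed, 86 higher and 6 lower, and each had every treated sample on one side of the vehicle mean. Among the largest increases were those in the lymphotoxin gene Ltb (log2 fold change 1.75 ± 0.48, adjusted p = 0.0239), the adhesion molecule Icam1 (1.71 ± 0.55), Il1b (1.69 ± 0.40, adjusted p = 0.0207), and Dusp2 (1.67 ± 0.41). Others were in Icosl (1.66 ± 0.42), S100a9 (1.65 ± 0.44, adjusted p = 0.0239), the histamine-forming enzyme Hdc (1.65 ± 0.46), S100a8 (1.65 ± 0.46) and the stress gene Gadd45b (1.63 ± 0.40). The 6 lower genes were the growth factor Tgfa (-0.56 ± 0.17, adjusted p = 0.0293), Pdgfra (-0.54 ± 0.19), Dusp6 (-0.47 ± 0.15), Rab3d (-0.47 ± 0.14), the transcriptional regulator Yap1 (-0.45 ± 0.15) and the kinase Fyn (-0.32 ± 0.11). Ptgs2 rose by 1.48 ± 0.42 (adjusted p = 0.0257) and Cxcr2 by 1.43 ± 0.38 (adjusted p = 0.0239), and Vegfa passed at 0.50 ± 0.17 (adjusted p = 0.0490). Arg1 (-0.17 ± 0.49, adjusted p = 0.817, positive with edgeR and lane factors or without triple combination sample a and vehicle sample 3) and Cd274 (1.29 ± 0.65, adjusted p = 0.160) did not pass. Nor did Cybb (0.52, adjusted p = 0.589), negative with TMM, or Stat3 (0.13, adjusted p = 0.422) and Tgfb1 (0.24, adjusted p = 0.466), both negative after median centring, quantile normalization or TMM.

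Of the 14 neutrophil genes 10 rose, and 13 when adjusted over the list alone (median 1.45, camera adjusted p = 6.38e-04, and adjusted p = 0.893 with an estimated correlation), led by Csf3r (1.56 ± 0.37). Of 22 NF-kB and TNF-induced genes 11 rose and 17 when adjusted over the list alone (median 1.29, camera adjusted p = 9.45e-04, and adjusted p = 0.893 with an estimated correlation), with Tnfaip3 at 1.58 ± 0.39, Nfkbia at 1.15 ± 0.30 and Nfkbiz at 1.06 ± 0.29. Of 14 chemokine receptors and adhesion molecules 9 rose and 11 when adjusted over the list alone (median 1.42, camera adjusted p = 0.00940, and adjusted p = 0.893 with an estimated correlation), among them Cxcr4 (1.55 ± 0.36), the selectin ligand Selplg (1.49 ± 0.40) and Ccrl2 (1.56 ± 0.42). Of 11 Fc receptor and phagocytosis genes 7 rose and 9 when adjusted over the list alone (median 1.20, camera adjusted p = 0.0224, and adjusted p = 0.893 with an estimated correlation), with Fcgr4 at 1.27 ± 0.38 and the signalling genes Tyrobp (1.46 ± 0.45), Syk (1.36 ± 0.42) and Vav1 (1.20 ± 0.39). None of these 4 list calls held with an estimated correlation. The lists share members, such as Cxcr2, Itgam and Itgb2. After median centring all 14 neutrophil genes had a positive fold change, with a median of 1.14. Of the 10 pan-leukocyte genes 8 rose (median 1.32), none of the 10 epithelial genes passed (median -0.25), and none of the 10 monocyte and macrophage markers passed (median 0.39). Of the endothelial (median 1.01) and dendritic cell markers (median 0.38, and -0.11 after quantile normalization and -0.029 with TMM) none passed, and of the 9 fibroblast and matrix genes Pdgfra fell and no other passed (0 over the list alone, median 0.48, and -0.23 with TMM).

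The median log2 fold change of all genes was 0.29, and the split of 86 higher and 6 lower was 83 and 8 after median centring, 69 and 32 after quantile normalization and 60 and 22 with edgeR and TMM factors. The count was 0 without vehicle samples V1 and V2, 1 without vehicle sample 1 or 4 or entinostat plus anti-PD-1 sample 1, 2 or 4, 13 without V1, 7 without V2 and 140 without vehicle sample 2. It was 43 without the background filter, 33 with edgeR and lane factors, 226 with sample weights and 1 with the epithelial mean or Cdh1 as a covariate. Within cartridge 1 it was 0 and with cartridge as a block 3, while the median log2 fold change over the 86 higher genes was 1.28 and 1.41 in those fits against 1.34 for all samples.

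Between entinostat plus anti-CTLA-4 and vehicle no gene passed. S100a9 stood at 5209 ± 4952 normalized counts (SD, n = 4) against 5879 ± 4373 in vehicle (SD, n = 6), a log2 fold change of -0.37 ± 0.44 (adjusted p = 0.960). Without sample a of the combination, which stood apart from its mates, it was at 2792 ± 1316 (SD, n = 3), a log2 fold change of -0.94 ± 0.37 (limma adjusted p = 0.154). By limma 0 of 420 genes passed, with 6 at an unadjusted p under 0.05, and edgeR also gave 0 with either set of factors. The genes with the smallest p, given as not passing, were Gata3 (0.40 ± 0.16), Tapbp (0.28 ± 0.14) and Peli1 (0.22 ± 0.11) in the higher direction and Ndufa7 (-0.32 ± 0.14), Vegfa (-0.40 ± 0.17) and Nr4a2 (-0.57 ± 0.26) in the lower, all with an adjusted p of 0.960. Arg1 had a log2 fold change of -0.95 ± 0.49, Ptgs2 of -0.53 ± 0.42, Cybb of -0.85 ± 0.64 and Cd274 of -0.41 ± 0.65, and none passed. For S100a8 the log2 fold change was -0.29 ± 0.46, for Cxcr2 -0.25 ± 0.38, for Tgfb1 -0.21 ± 0.22 and for Stat3 -0.080 ± 0.11, the last positive after median centring, quantile normalization or TMM, and none passed. No gene list was called with the preset correlation, and the neutrophil genes had a median log2 fold change of -0.38 (camera adjusted p = 0.200). Without sample a 3 lists were called lower, the neutrophil genes (median -0.94, camera adjusted p = 0.00218), the NF-kB genes and the Fc receptor and phagocytosis genes (adjusted p = 0.0215 for both), each with 0 members passing, and none held with an estimated correlation (adjusted p = 0.878 with an estimated correlation for each). The mean of the neutrophil list was 6.48 ± 1.22 (SD, n = 4) on the log2 scale, and 5.90 ± 0.49 (SD, n = 3) without sample a. Pan-leukocyte genes had a median of -0.52 and epithelial genes of 0.026, with none passing. The median log2 fold change of all genes was -0.13. With sample weights 18 genes passed. After median centring 4 lists were called, and without vehicle samples V1 and V2 3 lists.

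The triple combination against vehicle also gave 0 genes by limma, with 59 at an unadjusted p under 0.05 (50 higher and 9 lower) and 0 by edgeR with either set of factors. Without triple combination sample a and vehicle sample 3, whose lanes lay beside each other's group, limma also gave 0, with 120 at an unadjusted p under 0.05 (106 higher and 14 lower). With only the samples numbered 1 to 4, which leaves out samples V1, V2, a and b, 36 genes passed (35 higher and 1 lower). Of the triple combination this fit kept only sample 2, the sample of lowest depth, and sample 4. The mean of the pan-leukocyte genes was 7.19 in triple combination sample a and 7.72 to 7.98 in the others on the log2 scale, and 7.66 in vehicle sample 3 and 6.17 to 8.18 in the others. Among the genes with the smallest p in the higher direction were the mitotic kinase Ttk (log2 fold change 0.73 ± 0.21) and the immunoproteasome subunit Psmb9 (1.11 ± 0.32), each with an adjusted p of 0.281. In the lower direction they were Plau (-0.68 ± 0.18, adjusted p = 0.281), Nr2f6 (-0.51 ± 0.16) and Mif (-0.37 ± 0.12, adjusted p = 0.307 for both). S100a9 stood at 9488 ± 1398 normalized counts (SD, n = 4), a log2 fold change of 0.91 ± 0.44 (adjusted p = 0.338). S100a8 (0.95 ± 0.46), Cxcr2 (0.89 ± 0.38), Cd274 (1.21 ± 0.65), Cybb (0.71 ± 0.64), Ptgs2 (0.44 ± 0.42) and Arg1 (0.044 ± 0.49) did not pass, nor did Vegfa (0.17 ± 0.17), Tgfb1 (0.10 ± 0.22) and Stat3 (0.046 ± 0.11), which, like Arg1, were negative after median centring, quantile normalization or TMM.

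As lists, the 14 neutrophil genes (0 passing, and 0 when adjusted over the list alone) and the 10 interferon-gamma response genes (0 passing and 2 when adjusted over the list alone) stood apart from the other genes in the triple combination. Their median log2 fold changes were 0.86 and 0.53 (camera adjusted p = 0.0391 for both, and 0.960 with an estimated correlation). The mean of the interferon-gamma genes was highest in sample 2 of the combination, the sample of lowest depth (7.78 on the log2 scale). It was 7.39, 6.75 and 5.95 in samples 4, b and a, against 6.31 ± 0.47 in vehicle (SD, n = 6). Among the members with the smallest p were, of the neutrophil genes, the antimicrobial peptide gene Camp (1.23 ± 0.50), Csf3r (0.91 ± 0.37) and Cxcr2, and, of the interferon-gamma genes, Psmb9, Ifngr1 (0.49 ± 0.19) and Irf1 (0.52 ± 0.27). Pan-leukocyte genes had a median of 0.70 and epithelial genes of -0.099, with none passing in either, and the median of all genes was 0.30. Without vehicle samples V1 and V2 no list was called, only the interferon-gamma genes were called without triple combination sample a and vehicle sample 3, and only the neutrophil genes without entinostat plus anti-CTLA-4 sample a. After median centring 4 were called, and with sample weights 126 genes passed.

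The mean of the 4 entinostat groups against vehicle gave 3 genes, all higher: Il17ra, the IL-17 receptor (0.66 ± 0.13, adjusted p = 0.0265), Peli1, an E3 ubiquitin ligase of innate signalling (0.35 ± 0.080, adjusted p = 0.0434) and the growth factor Csf1 (1.03 ± 0.22, adjusted p = 0.0265). Of these, Peli1 had 16 of 16 treated samples above the vehicle mean. Il17ra and Csf1, each with 13 of 16, were named after their values were seen. At an unadjusted p under 0.05 there were 132 genes, edgeR gave 1 with TMM and 0 with lane factors, and the median log2 fold change of all genes was 0.23. The lower genes with the smallest p, Hist2h2aa1 (-0.33 ± 0.10, adjusted p = 0.0869), S100a4 (-0.37 ± 0.12) and Plau (-0.40 ± 0.13), did not pass. Cxcr2 (0.95 ± 0.28, adjusted p = 0.0869), S100a8 (1.04 ± 0.34), S100a9 (1.01 ± 0.33), Ptgs2 (0.68 ± 0.31), Cd274 (0.91 ± 0.48) and Arg1 (-0.26 ± 0.36) did not pass. Nor did Cybb (0.32 ± 0.48), negative with TMM, or Vegfa (0.18), Tgfb1 (0.16) and Stat3 (0.10), negative after median centring, quantile normalization or TMM. The neutrophil list (0 passing, 9 when adjusted over the list alone, median 0.89, camera adjusted p = 0.00437) and the NF-kB list (0 and 6, median 0.69, camera adjusted p = 0.0129) were called with the preset correlation and not with an estimated one (adjusted p = 0.895 with an estimated correlation for both). Among their members with the smallest p were Csf3r (1.00), Cxcr2 and S100a9, and Il1b (0.97), Tnfaip3 (0.91), Tnfaip6 (1.24) and Ikbke (0.75). Pan-leukocyte genes had a median of 0.77 and epithelial genes of -0.12. The count was 0 with only the samples numbered 1 to 4, without V1 and V2 together, without triple combination sample a and vehicle sample 3 together or without vehicle sample 1, 3, 4, V1 or V2 or entinostat plus anti-PD-1 sample 4. It was 127 without vehicle sample 2, and 13 and 17 without entinostat plus anti-CTLA-4 sample a or b. It was 19 after quantile normalization, 13 with a stricter filter, 5 after median centring, 194 with sample weights and 0 with the epithelial mean as a covariate. Without V1 and V2 no list was called, after median centring 4 were, and without entinostat plus anti-CTLA-4 sample a the chemokine receptors and adhesion molecules were called too (camera adjusted p = 0.0316, and adjusted p = 0.838 with an estimated correlation). Without that sample 3 of 14 neutrophil genes, 3 of 14 chemokine receptors and adhesion molecules and 0 of 22 NF-kB genes passed.

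Adding anti-PD-1 to entinostat changed 0 genes by limma, with 7 at an unadjusted p under 0.05 and 0 by edgeR with either set of factors. Hist2h2aa1 (0.49 ± 0.15) and S100a4 (0.46 ± 0.17) were among the genes with the smallest p in the higher direction and the DNA repair gene Ercc1 (-0.54 ± 0.17), Ski (-0.65 ± 0.25) and Egr3 (-0.48 ± 0.19) in the lower, each with an adjusted p of 0.971. Of the 6 genes of MHC class I antigen presentation none passed, and 0 when adjusted over the list alone (median 0.17), and the list was called with the preset correlation (camera adjusted p = 0.0426, and 0.187 with an estimated correlation). Its members with the smallest p were Tapbp (0.25 ± 0.15), Calr (0.19 ± 0.12), Tap1 (-0.29 ± 0.29), which turned positive with TMM, and Psmb8 (0.14 ± 0.21). The neutrophil genes had a median of -0.19 (camera adjusted p = 0.965), the epithelial genes of 0.12, the pan-leukocyte genes of -0.15 and all genes of -0.14. Both groups lay on cartridge 1. With sample weights 3 genes passed, after median centring 2 lists were called, and none was without triple combination sample a and vehicle sample 3 or without entinostat plus anti-CTLA-4 sample a.

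Adding anti-CTLA-4 to entinostat went with lower neutrophil and inflammatory genes, and with lower pan-leukocyte genes (median log2 fold change -1.96). S100a9 stood at 5209 ± 4952 normalized counts after entinostat plus anti-CTLA-4 (SD, n = 4) and 18565 ± 5130 after entinostat alone (SD, n = 4), a log2 fold change of -2.22 ± 0.48 (adjusted p = 0.00279), and it lay below the entinostat mean in 4 of 4 samples. Without sample a of the combination it was at 2792 ± 1316 (SD, n = 3), a log2 fold change of -2.78 ± 0.40 (limma adjusted p = 3.05e-05). In all 203 genes passed, 24 higher and 179 lower, of which 20 and 148 had every sample of the combination on one side of the entinostat mean. The 10 largest decreases were in Hdc (-2.47 ± 0.51, adjusted p = 0.00257), the itaconate-forming enzyme Acod1 (-2.42 ± 0.60), Sele (-2.42 ± 0.73), the formyl peptide receptors Fpr2 (-2.33 ± 0.53) and Fpr1 (-2.30 ± 0.47, adjusted p = 0.00257), and in 5 more. These were Ptprb (-2.30 ± 0.75), the basement membrane gene Hspg2 (-2.29 ± 0.62), Icosl (-2.27 ± 0.46), the prostaglandin E2 receptor Ptger2 (-2.24 ± 0.54) and Olr1 (-2.24 ± 0.49). Among the largest increases were those in Hist2h2aa1 (0.72 ± 0.15, adjusted p = 0.00257), Pdgfra (0.71 ± 0.21), the laminin gene Lamb3 (0.69 ± 0.28) and the receptor kinase Met (0.64 ± 0.21). Others were in Plau (0.59 ± 0.19), the chemokine Cx3cl1 (0.54 ± 0.19), Fzd6 (0.50 ± 0.19), Rab3d (0.47 ± 0.15) and S100a4 (0.46 ± 0.17).

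All 14 neutrophil genes fell, and 14 when adjusted over the list alone (median -2.07, camera adjusted p = 0.00239, and adjusted p = 0.839 with an estimated correlation), with Alox5 (-2.13 ± 0.45), Cxcr2 (-1.97 ± 0.42) and Trem1 (-2.16 ± 0.46) beside Fpr1. Of the 22 NF-kB and TNF-induced genes 19 fell, and 19 when adjusted over the list alone (median -1.72, camera adjusted p = 0.0156, and adjusted p = 0.839 with an estimated correlation), with Il1b at -2.02 ± 0.44, Nfkbiz at -1.43 ± 0.32, Tnfaip3 at -1.87 ± 0.42 and Birc3 at -2.09 ± 0.49. Of 14 chemokine receptors and adhesion molecules 12 fell, and 12 over the list alone (median -1.86, camera adjusted p = 0.0339, and adjusted p = 0.839 with an estimated correlation), among them Cxcr4 (-1.87), Selplg (-2.05) and Ccr1 (-1.94). Of 11 Fc receptor and phagocytosis genes 9 fell, and 9 over the list alone (median -1.71, camera adjusted p = 0.0339, and adjusted p = 0.839 with an estimated correlation), among them Vav1 (-2.11), Syk (-2.19), Clec7a (-2.10) and Tyrobp (-2.06). Of the 15 suppressive effectors 13 fell, and 13 over the list alone (median -0.99, camera adjusted p = 0.0339, and adjusted p = 0.839 with an estimated correlation), led by S100a9, Vegfa (-0.84), Cebpb (-1.02) and S100a8 (-2.12). After median centring 3 of them were lower and 5 of 15 fold changes were positive. No list call held with an estimated correlation, and the suppressive effectors were not called without sample a of the combination (camera adjusted p = 0.0576). No neutrophil gene had a positive fold change after median centring, quantile normalization or TMM, and 13, 12 and 13 passed as lower.

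Of the 10 pan-leukocyte genes 10 fell (median -1.96, and -1.24 after median centring), and of the 10 epithelial genes 5 rose (median 0.41, and 1.13 with 7 higher after median centring). None of the 10 monocyte and macrophage markers passed (median -1.23), while 7 of the 10 did without entinostat plus anti-CTLA-4 sample a (median -1.77). Of the 4 endothelial markers 2 fell, and 3 over the list alone (median -2.28, camera adjusted p = 0.600), Sele and the cadherin gene Cdh5 (-2.14 ± 0.78). Of the 4 dendritic cell markers 2 fell, and 4 over the list alone (median -1.19, camera adjusted p = 0.397), Itgax (-1.83 ± 0.50) and Fscn1 (-1.53 ± 0.45). Of the 9 fibroblast and matrix genes Timp3 (-1.42 ± 0.47) and Col1a2 (-1.40 ± 0.56) fell and Pdgfra rose, and 2 passed over the list alone (median -1.40, camera adjusted p = 0.542, with a higher direction than other genes). Without entinostat plus anti-CTLA-4 sample a 3 of 4 endothelial (median -3.06), 4 of 4 dendritic cell (median -1.51) and 6 of 9 fibroblast and matrix genes (median -1.82) passed. Cdh5, Itgax, Fscn1, Timp3 and Col1a2 were named after their values were seen. After median centring 1 endothelial and 1 dendritic cell marker were lower, and of the fibroblast and matrix genes 3 were higher and 0 lower. Of these 4 lists fry called the endothelial (adjusted p = 0.0415) and dendritic cell markers (adjusted p = 0.00505), both lower. The median log2 fold change of all genes was -0.67, and the split of 24 higher and 179 lower became 121 and 104 after median centring, 112 and 86 after quantile normalization, and 138 and 87 with edgeR and TMM factors. Each group lay on a cartridge of its own, so no value within a cartridge exists. With cartridge as a block, set by the vehicle and triple combination samples, 160 genes passed (5 higher and 155 lower) and the median over the 179 lower genes went from -1.70 to -1.91. The count was 134 without entinostat sample 3, 119 and 121 without entinostat plus anti-CTLA-4 sample 1 or b, 266 without its sample a, 320 with sample weights, 106 with the epithelial mean and 0 with Cdh1 as a covariate.

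The triple combination against entinostat alone gave 0 genes by limma, with 53 at an unadjusted p under 0.05 and 0 by edgeR with either set of factors. Among the genes with the smallest p were the kinase Jak3 (log2 fold change -0.86 ± 0.18, adjusted p = 0.0653), Il17ra (-0.67 ± 0.19) and Fpr1 (-1.61 ± 0.47, adjusted p = 0.323) in the lower direction and Nox4 (0.86 ± 0.29) and the cyclin Ccnb2 (0.41 ± 0.14) in the higher. With the preset correlation 4 lists were called, each with 0 members passing. Lower were the neutrophil genes (1 when adjusted over the list alone, median -0.82, camera adjusted p = 0.0180), the NF-kB genes (0, median -0.76, adjusted p = 0.0180) and the STAT3 and IL-6 family genes (0, median -0.58, adjusted p = 0.0360), and MHC class I antigen presentation (0, median 0.17, adjusted p = 0.0241) was higher. With an estimated correlation none held (adjusted p = 0.260 with an estimated correlation for MHC class I and 0.935 for the others). Without triple combination sample a and vehicle sample 3 2 lists were called, the neutrophil and the MHC class I genes. Members with the smallest p were Fpr1, Fpr2 (-1.28), Trem1 (-0.98) and Cxcr2 (-0.83) of the neutrophil genes, and Cxcl3 (-1.36), Nfkbiz (-0.74), Ccl4 (-1.03) and Nfkbia (-0.69) of the NF-kB genes. They were Cebpb (-0.58), Stat3 (-0.28, positive after median centring, quantile normalization or TMM), Il10ra (-1.04) and Lif (-0.67, positive with TMM) of the STAT3 list, and Psmb9 (0.65), Psmb8 (0.33), Calr (0.18) and Tapbp (0.15) of MHC class I. Pan-leukocyte genes had a median of -0.78, epithelial genes of 0.23 and all genes of -0.24. The count was 106 with sample weights, and 3 after quantile normalization or without entinostat plus anti-CTLA-4 sample a. It was 1 without vehicle sample 2 or V2, entinostat plus anti-CTLA-4 sample 1 or triple combination sample b. It was also 1 with only the 2 groups in the fit, with V1 and V2 averaged into samples 1 and 2, or with a stricter filter.

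Within the antibody combinations limma called 0 genes. The triple combination against entinostat plus anti-PD-1 had 33 genes at an unadjusted p under 0.05 and 0 by edgeR with either set of factors. Its smallest p belonged to Ercc1 (0.49 ± 0.17), Gata3 (0.47 ± 0.18) and Smad1 (0.48 ± 0.18) in the higher direction and Map2k1 (-0.41 ± 0.12), Adgre5 (-0.44 ± 0.15) and Il17ra (-0.57 ± 0.19) in the lower, each with an adjusted p of 0.602. The triple combination against entinostat plus anti-CTLA-4 had 115 (111 higher) and 0 by edgeR. Among the genes with the smallest p were Sp4 (0.80 ± 0.21) and Was (1.40 ± 0.37) in the higher direction (adjusted p = 0.148 for both), and Plau (-0.67 ± 0.19), Tgfa (-0.50 ± 0.19) and Hist2h2aa1 (-0.32 ± 0.15) in the lower. Its count was 191 without entinostat plus anti-CTLA-4 sample a, 31 without triple combination sample a, 35 without that sample and vehicle sample 3, 120 without both that anti-CTLA-4 sample and the sample of lowest depth, 207 with sample weights and 41 with the epithelial mean as a covariate. It was 214 with only the samples numbered 1 to 4 (194 higher and 20 lower). Those are only triple combination samples 2, of lowest depth, and 4, and entinostat plus anti-CTLA-4 samples 1 and 3. The interaction of the antibodies, which asks whether their effects add on the log2 scale in entinostat-treated mice, had 0 genes, 81 at an unadjusted p under 0.05 and 0 by edgeR. Among the genes with its smallest p were Ercc1 (0.84 ± 0.24, adjusted p = 0.250) and Sp4 (0.94 ± 0.29, negative after quantile normalization) in the positive direction and Hist2h2aa1 (-0.81 ± 0.21), Plau (-0.96 ± 0.27) and Cx3cl1 (-0.64 ± 0.27) in the negative. Its count was 152 without entinostat plus anti-CTLA-4 sample a, 80 without that sample and the one of lowest depth, 1 without entinostat plus anti-PD-1 sample 1, 197 with only the samples numbered 1 to 4 (179 positive and 18 negative) and 239 with sample weights. The median log2 fold change of all genes was -0.064, 0.45 and 0.61 in these 3 comparisons.

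Over all 5 groups, the moderated F test of limma called 139 of 420 genes (192 at an unadjusted p under 0.05). It called 0 with cartridge as a block, where the smallest adjusted p was 0.0525. It called 211 without entinostat plus anti-CTLA-4 sample a, 317 with sample weights, 57 with the epithelial mean and 0 with Cdh1 as a covariate (smallest adjusted p 0.0541), and 81 with edgeR and lane factors.

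Across the 22 samples, the mean of the 10 epithelial genes and the mean of the 14 neutrophil genes were negatively related (Pearson's r = -0.62, permutation p = 0.0021; Spearman's rho = -0.67, permutation p = 0.00091; Benjamini-Hochberg adjusted p = 0.0064 over 10 relations). Without the 2 samples farthest from the median of the epithelial mean r was -0.62 (permutation p = 0.0032, n = 20). Within cartridge 1 it was -0.74 (permutation p = 0.0042, adjusted p = 0.0070, n = 12) and within cartridge 2 it was -0.19 (permutation p = 0.60, n = 10), where the relation missed the threshold. A difference between the cartridges was not tested, and Cdh1 alone was not among the 10 relations. For deviations from the group means r was -0.53 (permutation p = 0.016, adjusted p = 0.023, n = 22). The epithelial and the monocyte and macrophage means gave r = -0.61 over all samples (permutation p = 0.0027, adjusted p = 0.0064) and rho = -0.56 (permutation p = 0.0079). Without the 2 farthest samples r was -0.52 (permutation p = 0.019, n = 20), and for deviations from the group means -0.64 (permutation p = 0.00073). It was -0.87 within cartridge 1 (permutation p = 0.00024) and -0.37 within cartridge 2 (permutation p = 0.30), where this relation also missed the threshold.

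**Figure D3:**
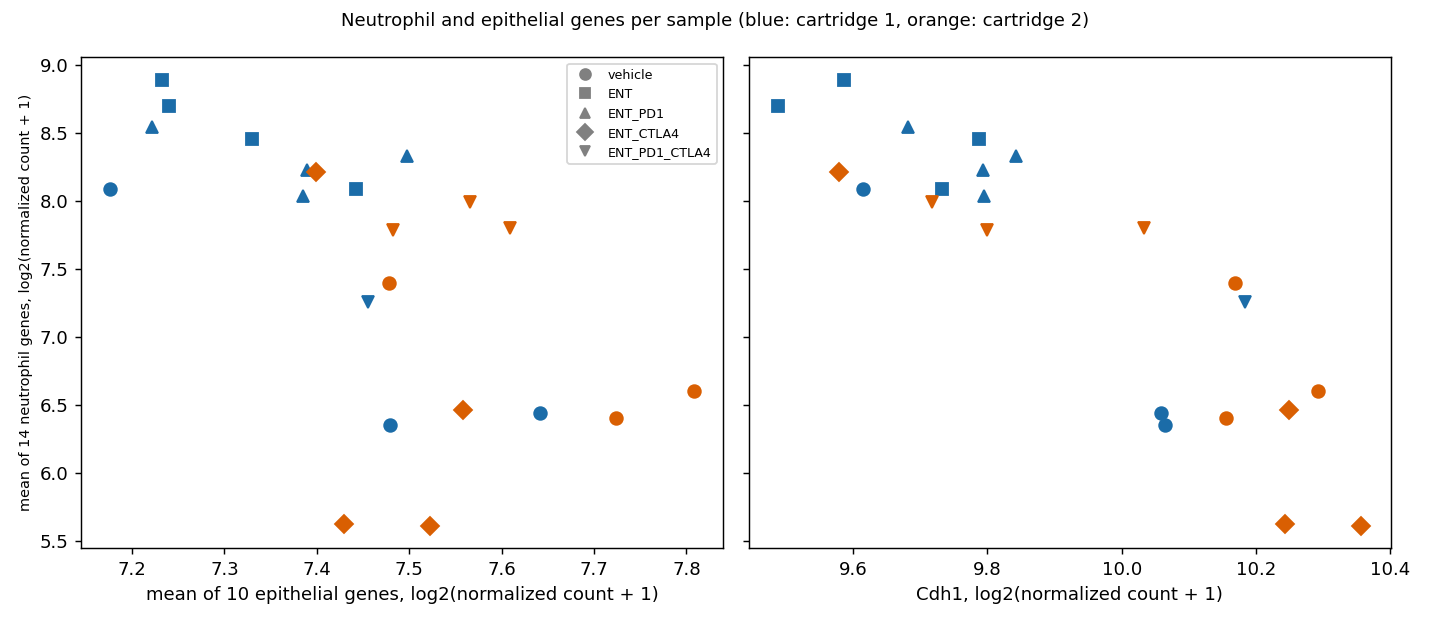
Mean of the 14 neutrophil genes (vertical axis) against the mean of the 10 epithelial genes (left) and Cdh1 (right), all as log2(normalized count + 1), for each of the 22 samples; marker shape gives the group and colour the cartridge (blue 1, orange 2). The list gave r = -0.62 over all samples and -0.19 within cartridge 2. Cdh1 is drawn because it was looked at first, after its values had been seen, and no correlation was calculated for it. On cartridge 2 the lowest Cdh1, 9.58 in entinostat plus anti-CTLA-4 sample a, went with the highest neutrophil mean, 8.21. The highest Cdh1, 10.36 in sample b of that group, went with the lowest neutrophil mean, 5.61.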

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

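The tests of epithelial share, cartridge, scaling, direct change and sample label and the splits within a cartridge were chosen only after the results were seen, and the counts over other splits of the samples were planned before. A total of 105 sets of values (21 measures in 5 groups) were searched for a sample far from the rest of its group, and 6 were found where chance gives 5.25.

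In vehicle sample 2, S100a8 and S100a9 took 8.40% of all counts (95% Wilson interval 8.29 to 8.52, counting error only), against 2.60% to 4.21% in the other vehicle samples. The same sample had the highest vehicle level of Cxcr2 (8.68 on the log2 scale, nearest 7.46) and the lowest of Cdh1 (9.61, nearest 10.06). Entinostat plus anti-CTLA-4 sample a had a median endogenous level of 59.1 normalized counts (nearest 28.9), the highest Tgfb1 of its group (8.37, nearest 7.68) and the lowest Cdh1 (9.58, nearest 10.24). The effects of entinostat alone and of entinostat plus anti-CTLA-4 against vehicle differed in 203 genes by the direct comparison of these groups. Of the 20 housekeeping genes, whose geometric mean was nearly level in the deposited values, 9 passed between entinostat and vehicle (4 higher and 5 lower), 6 between entinostat plus anti-CTLA-4 and entinostat (3 and 3) and 1, lower, between the triple combination and entinostat.

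Of the 152 genes higher after entinostat than in vehicle, 139 were also called higher with cartridge as a block, which argues against cartridge as the whole cause. After median centring 95 of the 152 were called higher, after quantile normalization 88 and with edgeR and TMM 57. Their median log2 fold change of 1.36 became 0.82, 0.74 and 0.58. These scalings remove a shift shared by most genes by construction, so the smaller folds cannot show that the deposited scaling was the cause. Scaling to the housekeeping genes stays open. From the difference in the 10 epithelial genes, slopes within groups predicted 0.333 of the observed fold at the median gene (0.249 to 0.423 with each sample left out), and from Cdh1, tried first and picked after its values were seen, 0.611, too much to exclude a difference in epithelial share, although selection for Ly6G should deplete epithelial cells and Cdh1 stood at 1077 ± 159 normalized counts in vehicle. With the epithelial mean as a covariate 0 genes passed in limma (83 of the 152 at an unadjusted p under 0.05), more through smaller folds (median log2 fold change 1.36 with an SD across genes of 0.52 before and 0.84 with 0.38 after, median ratio 0.667) than through larger errors (median ratio of the SE 1.09). The covariate overlaps with the treatment (correlation 0.573 in size), so a direct change of transcript levels and epithelial share cannot be told apart for these genes, and chance stays open too, since 2 of 35 splits within a cartridge gave as many genes.

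For the 179 genes lower after entinostat plus anti-CTLA-4 than after entinostat alone, groups on separate cartridges, the median fold with cartridge as a block was 1.12 times that without it, which argues against cartridge as the whole cause, as far as the vehicle and triple combination samples carry the cartridge difference. The epithelial genes predicted 0.196 of the fold (0.128 to 0.260 with each sample left out), while Cdh1 predicted 0.591. These measures disagree, and the log2 fold changes of the epithelial genes ran from -0.73 to 0.69, so epithelial share was not excluded. Of the 179 genes 104 were called lower after median centring, 86 after quantile normalization and 87 with edgeR and TMM, and their median log2 fold change of -1.70 became -0.98, -0.75 and -0.89. Here too these scalings remove a shared shift by construction and cannot decide the question. Scaling to the housekeeping genes stays open, as do an effect of anti-CTLA-4 and chance, since 2 of 35 splits gave as many genes.

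Entinostat plus anti-CTLA-4 sample a stood apart from its 3 mates. It correlated best with entinostat sample 1 (r = 0.980 across genes, which are not independent replicates), and its best mate ranked 18 of the 21 other samples, as a wrong label would give. Its pan-leukocyte mean was 7.95 on the log2 scale, against 5.78 to 6.59 in its mates. In the search for repeats vehicle sample 2 also correlated better with another group (r = 0.986, entinostat plus anti-PD-1 sample 4) than with any vehicle sample (at most 0.950). Such a rank alone does not single out a wrong label. The epithelial genes predicted 0.0977 of the deviation of sample a, while Cdh1 predicted 0.758. The epithelial mean of sample a differed from that of its mates by only -0.104 on the log2 scale, and Cdh1 by -0.704. These measures disagree, and so small a difference in the epithelial mean can predict little, so epithelial share was not excluded. A wrong label may be weighed beside it and was not shown. The column name of sample a stood on 2 columns, and no biological explanation was tested.

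Other splits of the same samples were counted for each comparison. With no regard to cartridge, few splits reached the real count for entinostat against vehicle (168 genes, highest other split 129, 1 of 100 splits as large) and entinostat plus anti-PD-1 against vehicle (92, highest other 72, 1 of 100). The same held for the mean of the entinostat groups (3, although the highest other split gave 123, 3 of 100 splits as large) and the F test (139, highest other 157, 2 of 100). Cartridge was not balanced over these groups, so splits that exchange samples only within a cartridge were counted too, and by these chance could not be excluded for the first 3. Of 35 such splits 2, the real one included, were as large for entinostat (highest other 215, with vehicle sample 2 exchanged for entinostat sample 4) and 2 for entinostat plus anti-PD-1 (127, with vehicle sample 2 exchanged for sample 3 of the combination), and of 100 drawn 5 were for the mean (233). The mean, at 3 genes with cartridge as a block, fell to 0 without any 1 of vehicle samples 1, 3, 4, V1 and V2 or entinostat plus anti-PD-1 sample 4. For the F test 4 of 100 were as large (148), a smaller share than for the others, but with cartridge as a block 0 genes passed (smallest adjusted p 0.0525). Chance could not be excluded for entinostat plus anti-CTLA-4 against entinostat (203, highest other 266, 2 of 35), where the higher split put sample a of the combination with entinostat samples 1, 2 and 3 and entinostat sample 4 with the combination. Where 0 genes passed, every split is as large by construction, so these counts could say nothing about chance: entinostat plus anti-CTLA-4 against vehicle (100 of 100, highest other 206), the triple combination against vehicle (100 of 100, 159) and the interaction (100 of 100, 232). It was 35 of 35 for entinostat plus anti-PD-1 against entinostat (highest other 0), the triple combination against entinostat (1), against entinostat plus anti-PD-1 (1) and against entinostat plus anti-CTLA-4 (263). For the mean of the entinostat groups, where 3 genes passed, other splits called up to 123 genes, and up to 233 within cartridges. The reason was not tested.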

How the results depend on the processing

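Cartridge, edgeR, the covariates, the fit without the block on the numbered samples, the joint removals of 2 samples and the list calls without entinostat plus anti-CTLA-4 sample a were chosen only after the results were seen, and the other alternatives were chosen before. The cause of each change was not tested, except that leaving out samples also lowers the number of samples. Calls were lost with V1 and V2 left out (entinostat against vehicle 54, entinostat plus anti-PD-1 against vehicle 0, treated mean 0, with lists called 0 for the triple combination and 0 for the treated mean) and with a covariate, while entinostat plus anti-CTLA-4 against vehicle gained 3 lists without V1 and V2. The epithelial mean gave 0, 1, 0, 106 and 57 genes for entinostat, entinostat plus anti-PD-1 and the treated mean against vehicle, entinostat plus anti-CTLA-4 against entinostat and the F test, and raised the triple combination against entinostat plus anti-CTLA-4 from 0 to 41. Cdh1 gave 2, 1, 0 and 0 for entinostat and entinostat plus anti-PD-1 against vehicle, entinostat plus anti-CTLA-4 against entinostat and the F test. Cartridge as a block gave 3 for entinostat plus anti-PD-1 against vehicle (0 within cartridge 1) and 0 for the F test. Sample weights raised all counts that moved: 298, 226, 18, 126 and 194 for entinostat, its pairs with anti-PD-1 and with anti-CTLA-4, the triple combination and the treated mean against vehicle. They gave 3, 320 and 106 for the same combinations against entinostat, 207 for the triple combination against entinostat plus anti-CTLA-4, 239 for the interaction and 317 for the F test. edgeR gave 33 for entinostat plus anti-PD-1 against vehicle and 81 for the F test with lane factors, and for the treated mean 1 with TMM and 0 with lane factors. The treated mean gave 5 after median centring, 19 after quantile normalization and 13 with the stricter filter. The triple combination against entinostat gave 1 with V1 and V2 averaged, with only the 2 groups or with the stricter filter, and 3 after quantile normalization. No filter gave 43 for entinostat plus anti-PD-1 against vehicle. Removal of the sample of lowest depth and entinostat plus anti-CTLA-4 sample a gave 120, 80 and 211 for the triple combination against entinostat plus anti-CTLA-4, the interaction and the F test. Removal of triple combination sample a and vehicle sample 3 gave 35 for the triple combination against entinostat plus anti-CTLA-4 and 0 for the treated mean, with lists called 6 for entinostat against vehicle, 1 for the triple combination against vehicle, 0 for entinostat plus anti-PD-1 against entinostat and 2 for the triple combination against entinostat. Removal of entinostat plus anti-CTLA-4 sample a gave 5, 3 and 1 lists for entinostat, entinostat plus anti-CTLA-4 and the triple combination against vehicle and 0 for entinostat plus anti-PD-1 against entinostat.

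With each sample left out in turn the counts ran from 80 to 207 for entinostat against vehicle, 1 to 140 for entinostat plus anti-PD-1 against vehicle, 0 to 127 for the treated mean, and 119 to 266 for entinostat plus anti-CTLA-4 against entinostat. They ran from 0 to 3 for the triple combination against entinostat, 0 to 191 for it against entinostat plus anti-CTLA-4, 0 to 152 for the interaction and 97 to 211 for the F test, and stayed at 0 for the other 4 comparisons. An estimated correlation left 0 lists in every comparison. fry called 13 lists for entinostat and 6 for entinostat plus anti-PD-1 against vehicle, 18 for entinostat plus anti-CTLA-4 against entinostat and 0 elsewhere. Median centring gave 4 lists for entinostat, entinostat plus anti-CTLA-4, the triple combination and the treated mean against vehicle and 2 for entinostat plus anti-PD-1 against entinostat.

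Equal replicate numbers did not pair the samples: of 24 same-number pairs 10 had a correlation over 0.1 (from -0.54 to 0.53), and 2 of 16 numbered samples correlated best with their own number. On the numbered samples, with the replicate block and without it, counts were 6 and 36 for the triple combination against vehicle, 0 and 0 for the treated mean, 73 and 214 for the triple combination against entinostat plus anti-CTLA-4, and 56 and 197 for the interaction. These fits kept only samples 1 and 3 of entinostat plus anti-CTLA-4 and samples 2 and 4 of the triple combination. Signs turned with the replicate block in Arg1 -0.022 for entinostat against vehicle, Arg1 -0.28, Ptgs2 -0.30, Stat3 -0.060 for the triple combination against vehicle and Cybb -0.15 for the treated mean against vehicle, and on the same samples with no replicate block in Arg1 -0.022 for entinostat against vehicle, Arg1 -0.061, Ptgs2 -0.22, Stat3 -0.087 for the triple combination against vehicle and Cybb -0.15 for the treated mean against vehicle.

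Of the single genes named, 26 results changed sign under at least 1 alternative, in 109 cases, while 7923 cases stayed on their side of the threshold, 821 lost a call and 183 gained one. Values are log2 fold changes. Without V1 and V2 the values were Arg1 -0.022 for entinostat against vehicle, Arg1 -0.024, Stat3 -0.020, Tgfb1 -0.029 for the triple combination against vehicle and Cybb -0.17 for the treated mean against vehicle. After median centring the values were Arg1 -0.49, Stat3 -0.21, Tgfb1 -0.042, Vegfa -0.092 for entinostat against vehicle, Stat3 -0.18, Tgfb1 -0.065 for entinostat plus anti-PD-1 against vehicle. The others were Stat3 0.099 for entinostat plus anti-CTLA-4 against vehicle, Arg1 -0.19, Stat3 -0.19, Tgfb1 -0.13, Vegfa -0.065 for the triple combination against vehicle, Stat3 -0.12, Tgfb1 -0.066, Vegfa -0.046 for the treated mean against vehicle and Stat3 0.027 for the triple combination against entinostat. After quantile normalization the values were Arg1 -0.67, Stat3 -0.20, Tgfb1 -0.079, Vegfa -0.15 for entinostat against vehicle, Stat3 -0.36, Tgfb1 -0.22 for entinostat plus anti-PD-1 against vehicle. The others were Stat3 0.071 for entinostat plus anti-CTLA-4 against vehicle, Arg1 -0.53, Stat3 -0.14, Tgfb1 -0.15, Vegfa -0.12 for the triple combination against vehicle, Stat3 -0.15, Tgfb1 -0.14, Vegfa -0.14 for the treated mean against vehicle, Sp4 -0.13 for the interaction and Stat3 0.058 for the triple combination against entinostat. With edgeR and TMM the values were Arg1 -0.71, Stat3 -0.35, Cybb -0.094, Tgfb1 -0.20, Vegfa -0.24 for entinostat against vehicle, Stat3 -0.27, Cybb -0.12, Tgfb1 -0.16 for entinostat plus anti-PD-1 against vehicle. The others were Stat3 0.022 for entinostat plus anti-CTLA-4 against vehicle, Arg1 -0.35, Stat3 -0.23, Tgfb1 -0.20, Vegfa -0.12 for the triple combination against vehicle, Stat3 -0.21, Cybb -0.27, Tgfb1 -0.17, Vegfa -0.14 for the treated mean against vehicle, Lif 0.13, Stat3 0.12 for the triple combination against entinostat and Tap1 0.013 for entinostat plus anti-PD-1 against entinostat. With edgeR and lane factors the values were Arg1 -0.093 for entinostat against vehicle, Arg1 0.012 for entinostat plus anti-PD-1 against vehicle and Arg1 -0.20 for the triple combination against vehicle. With the epithelial mean as a covariate the values were Arg1 -0.65, Cybb -0.070 for entinostat against vehicle, Cybb -0.20, Tgfb1 -0.0082 for entinostat plus anti-PD-1 against vehicle. The others were Arg1 -0.024 for the triple combination against vehicle and Cybb -0.20, Tgfb1 -0.023 for the treated mean against vehicle. With Cdh1 as a covariate the values were Arg1 -0.35, Cybb -0.46 for entinostat against vehicle, Cybb -0.41, Tgfb1 -0.070 for entinostat plus anti-PD-1 against vehicle. The others were Arg1 -0.079, Tgfb1 -0.035 for the triple combination against vehicle and Cybb -0.32, Tgfb1 -0.055 for the treated mean against vehicle. With cartridge as a block the values were Arg1 0.032 for entinostat plus anti-PD-1 against vehicle and Arg1 -0.057 for the triple combination against vehicle. Within cartridge 1 the values were Arg1 0.061 for entinostat plus anti-PD-1 against vehicle. Without triple combination sample a and vehicle sample 3 the values were Arg1 0.022 for entinostat plus anti-PD-1 against vehicle. Within cartridge 2 the values were Arg1 -0.11 for the triple combination against vehicle. Without the sample of lowest depth and entinostat plus anti-CTLA-4 sample a the values were Arg1 -0.15 for the triple combination against vehicle. With sample weights the values were Arg1 0.015 for the treated mean against vehicle. With each sample left out in turn the fold changes ran over Arg1 -0.18 to 0.28 for entinostat against vehicle, Arg1 -0.73 to 0.14 for entinostat plus anti-PD-1 against vehicle, S100a8 -0.86 to 0.056 for entinostat plus anti-CTLA-4 against vehicle. They also ran over Cxcr2 -0.76 to 0.087 for entinostat plus anti-CTLA-4 against vehicle, Arg1 -0.18 to 0.28 for the triple combination against vehicle, Tgfb1 -0.0057 to 0.23 for the triple combination against vehicle. Depth limits genes near background in triple combination sample 2, where 1 barcode count was worth 9.78 normalized counts.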

Other observations

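No explanation was tested for the values here, and the correlations of 2 single samples and the lists without a sample were chosen after the results were seen. Gene groups not described above moved as follows between entinostat and vehicle. Of 13 chemokine ligands 6 rose (7 adjusted over the list alone, median 1.47, camera adjusted p = 0.430), with Ccl8 and Ccl7 among them. Of 10 toll-like receptor and inflammasome genes 6 rose (6 over the list alone, median 1.17, adjusted p = 0.430), of 14 STAT3 and IL-6 family genes 9 (10, 1.10, 0.0599), of 14 chemokine receptors and adhesion molecules 11 (12, 1.48, 0.0599) and of 11 Fc receptor and phagocytosis genes 9 (9, 1.26, 0.0599). Interferon-gamma response genes passed in 4 of 10 (4, 0.73, 0.242), type I interferon genes in 2 of 3 (2, 0.71, 0.430), complement in 3 of 8 (3, 0.71, 0.661), MHC class II and co-stimulation in 2 of 10 (2, 0.79, 0.683) and immune checkpoints in 1 of 6 (1, 0.40, 0.777). Apoptosis and survival genes rose in 4 of 8 (4, 0.39, 0.935) and cell cycle genes in 1 of 5 (1, 0.25, 0.661). Angiogenesis and hypoxia genes rose in 4 and fell in 1 of 11 (5, 0.061, 0.430), growth factor receptors rose in 3 and fell in 1 of 7 (4, 0.60, 0.661) and MHC class I genes fell in 1 of 6 (1, -0.030, 0.173). None of these lists was called by camera, although without entinostat plus anti-CTLA-4 sample a the STAT3, chemokine receptor and Fc receptor lists were (adjusted p = 0.0494, 0.0460 and 0.0494, and adjusted p = 0.908 with an estimated correlation for each), while fry, which does not compare a list with other genes, called 9 of the 15, all higher. Without triple combination sample a and vehicle sample 3 camera also called the STAT3, chemokine receptor and Fc receptor lists. Relative to all other genes camera gave a lower direction for immune checkpoints, angiogenesis and hypoxia, apoptosis and survival, and cell cycle genes, while their medians were positive, and the mean of the MHC class I genes was positive (0.064) while their median was negative.

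Triple combination sample a correlated best with entinostat plus anti-CTLA-4 sample 3 (r = 0.977 across the 420 genes, which are not independent replicates), and its best mate ranked 3 of the 21 other samples. Its mean r was 0.954 with the vehicle samples and 0.922 with its mates, among them the sample of lowest depth. Vehicle sample 3 correlated best with triple combination sample b (r = 0.949 across genes), its best mate ranked 3, and its mean r was 0.924 with the triple combination samples and 0.925 with its mates. Between entinostat and vehicle, camera gave the fibroblast and matrix markers and the monocyte and macrophage markers a lower direction than other genes, while their medians were positive. The lists of NADPH oxidase genes, histone deacetylases, T and NK cells, B cells, tumour epithelium, and eosinophils, basophils and mast cells had fewer than 3 genes above background and were not tested. The first principal component of the tested genes held 73.9% of the variance and the second 5.86%.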
